A study of Homo sapiens with 16 samples.

How the data were processed

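Whole skin punch biopsies from 4 acral sites were kept in a stabilising solution, RNA was extracted with a column kit for fibrous tissue, and the product of random-primed amplification was hybridised to Affymetrix exon arrays, per the labels' protocols. The authors' deposited table holds log2 gene-level values for 44726 features in 16 arrays. Affymetrix Expression Console, the PLIER summary and genome build hg19 are named per the submitters' processing notes, with versions not given in the sources used here. Whether and how the arrays were scaled to each other is not stated. The log base was read from the values, which run from 1.90 to 13.59 with no missing value, and no pair of arrays held identical values.

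Arrays were grouped by the site, volar and extremity labels alone. The labels share replicate numbers 1 to 4 between sites without saying that a number is 1 donor, so the number was not used as a block except as an alternative. Features were given gene symbols from the platform annotation, updated through Entrez identifiers with a RefSeq table. Of all features, 21292 had exactly 1 symbol, 4327 had several and 19107 had none. Of those with exactly 1 symbol, 41 sex-linked features named in advance were left out because the donors are human. The test used the other 21251 features in 17384 genes, with no filter on level and no further normalization.

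One limma model (limma 3.58.1 in R 4.3.3, with data.table version 1.17.8) of the 4 site means gave all comparisons, with 12 residual degrees of freedom, moderated variances, 2-sided tests and Benjamini-Hochberg adjustment at 0.05. The factors were volar minus non-volar, upper minus lower extremity and their interaction, with 4 comparisons of single sites. Errors of differences are standard errors from that model. The method was tested on simulated data of the same size, with independent normal noise of equal spread in all sites. At a change of 1 on the log2 scale it recovered 95 of 100 features for each factor, 79 for the interaction and 87 for sole minus back of foot, with 8 to 13 false calls.

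The 36 gene lists covered epidermis, skin appendages, pigment cells, dermis, vessels, nerves, immune cells, positional factors and signalling. Each gene was represented by its feature with the highest mean, and 34 lists had at least 4 measured members. Camera with a preset correlation of 0.01 set each list against all other genes, adjusted over 68 tests, with camera at an estimated correlation and fry beside it. Groups, tests, lists, alternatives and the choice of named genes were set before the data were examined, unless stated otherwise. Named genes are the 10 highest and the 10 lowest called differences of each factor that share their sign in both simple effects, 14 genes named in advance, up to 4 members of smallest p per list, the 6 smallest p of the interaction, and the 3 highest and 3 lowest of each single-site comparison. Of the 10 lowest for the extremity 2 are not named, nor is 1 of the 3 lowest of palm minus sole, and SPINK6, CSRP2, FABP5, KRT1 and the cell line markers named singly were chosen for naming after their values were seen. Members of each list were also counted with p values adjusted over the list alone.

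Alternatives were a filter at the 40th percentile of mean level, quantile normalization on top, all features of the table, a fit of only the compared sites, the replicate number as a block, estimated array weights, a trended robust prior, the mean over features of a gene, an estimated correlation for the lists, a minimum absolute difference of 1, and each array left out in turn. A threshold relative to the median for the cell line markers was added after the data were seen. Offsets before a log transform were not run, since the values are logarithmic already. Differences in KRT9 between labels or numbers were tested by exact permutation, and correlations of deviations from site means by 100000 permutations within sites. Other splits of the arrays were counted in 100 random draws, or in all 35 splits for 8 arrays. The Fisher test of cell line markers relative to the median used SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15. Raw scans and exon-level values were not used here.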

Results

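Gene expression was measured in 16 whole skin biopsies, 1 per exon array, from 4 acral sites with 4 replicates each. Palm and sole are volar sites, the ridged and hairless skin of hand and foot, and the backs of hand and foot are non-volar. The labels cross volar and non-volar skin with the upper and the lower extremity, which leaves 8 arrays on each side of either comparison. The series description states that the replicates of each site came from distinct donors. An array has no read depth, so the number of arrays limits the precision. Positions are not given because the annotation tables used here come from different genome builds. Because a marker of volar skin, keratin 9 (KRT9), did not follow the site labels, groups are called by their labels throughout.

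The arrays fell into separate sets by labelled extremity before any gene was tested. The first principal component held 68.1% of the variance and parted the 8 arrays labelled palm or back of hand from the 8 labelled sole or back of foot, and the second held 6.12%. Pearson correlations across features, which are not independent replicates, lay between 0.969 and 0.987 among arrays labelled upper extremity and between 0.911 and 0.946 among those labelled lower extremity. Pairs with 1 array of each lay between 0.781 and 0.882. Values spread more widely across features in the arrays labelled upper extremity, with an SD of 1.25 ± 0.021 (SD, n = 8) against 1.04 ± 0.053 (SD, n = 8), and these ranges (1.21 to 1.27 and 0.947 to 1.10) did not overlap. Median levels per array were 3.87 ± 0.010 and 4.02 ± 0.038 on the log2 scale (SD, n = 8 each). The median SD of a feature within a group was 0.105 for arrays labelled palm, 0.081 for back of hand, 0.172 for sole and 0.162 for back of foot.

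**Figure D1:**
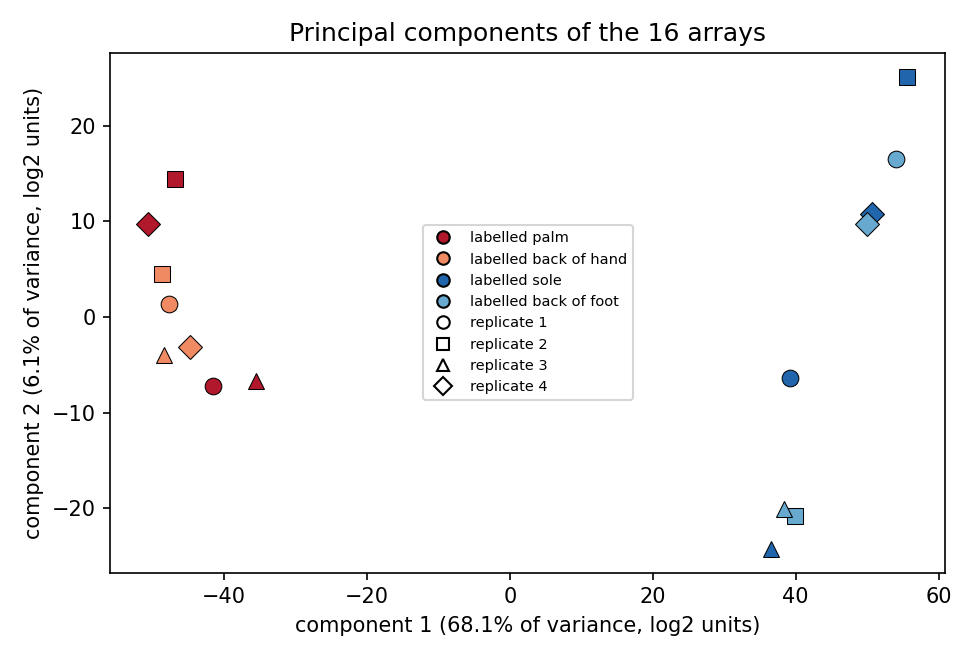
Principal components of the 16 arrays from 21251 features, with component 1 (68.1% of the variance) on the horizontal axis and component 2 on the vertical axis, both in log2 units; each point is 1 array, coloured by labelled site and shaped by replicate number. The arrays labelled palm and back of hand lie on the left and those labelled sole and back of foot on the right.

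Volar against non-volar skin is the comparison named in the series title. No gene passed the test between the 8 arrays labelled palm or sole and the 8 labelled back of hand or back of foot. KRT9, the keratin that marks the suprabasal epidermis of palms and soles (feature 3757138), differed by 0.05 on the log2 scale (SE 1.42, 95% interval -2.98 to 3.08), far less than its spread within each site. Its level was high in replicates 1 and 4 of every labelled site. In the arrays labelled palm it was 11.63, 5.33, 7.65 and 10.58 in replicates 1 to 4, and in those labelled back of hand 11.50, 6.59, 4.62 and 11.23. The arrays labelled sole had 11.89, 8.47, 5.45 and 11.83, and those labelled back of foot 12.07, 9.12, 5.32 and 11.97. The labelled volar difference in KRT9 had a 2-sided exact permutation p of 0.964 over 4900 arrangements within each labelled extremity.

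**Figure D2:**
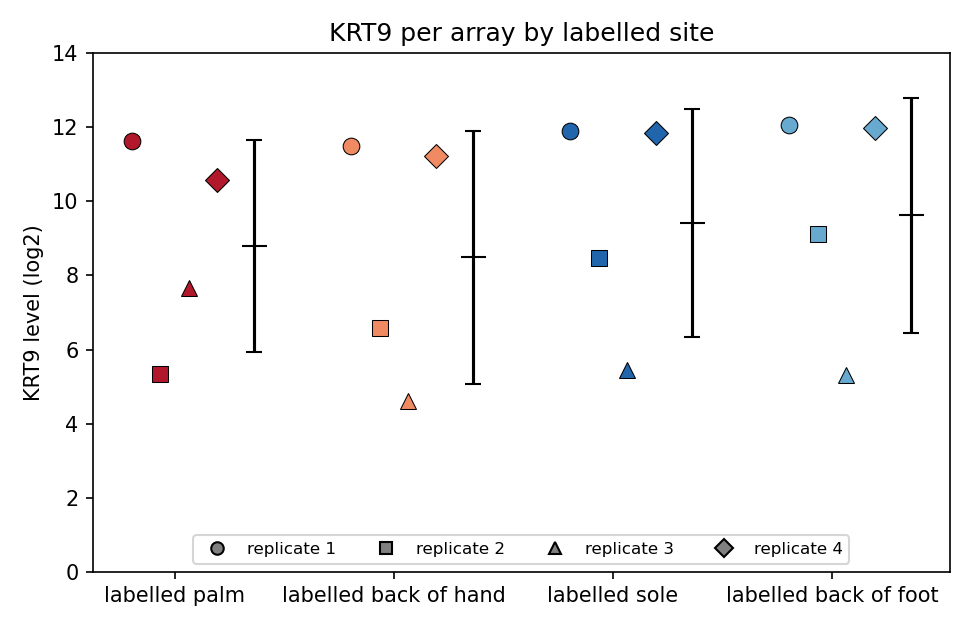
KRT9 level (log2, vertical axis) in each of the 16 arrays, grouped by labelled site, with a marker shape per replicate number; the bar at the right of each group is the mean with its SD (n = 4). Replicates 1 and 4 lie between 10.58 and 12.07 in every labelled site, and replicates 2 and 3 between 4.62 and 9.12.

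None of the other genes chosen in advance passed the volar test. LMX1B, the dorsal limb factor, was 0.37 higher in the arrays labelled volar (SE 0.15, limma unadjusted p 0.0232), and EN1, the ventral limb factor, and WNT7A, the dorsal signal, differed by 0.01 and 0.02. The LMX1B difference lay in the foot, with 5.83 to 6.85 in sole and 5.29 to 5.92 in back of foot. Palm and back of hand had 5.02 to 5.68 and 5.15 to 5.58. DKK1, a Wnt antagonist, differed by 0.02 (SE 0.06) and MITF, the master regulator of melanocytes, by -0.01 (SE 0.07). The positional genes HOXC9, HOXC10, HOXC11 and HOXD13 differed by 0.16, 0.00, -0.01 and -0.11, and the limb type factors TBX5, TBX4 and PITX1 by -0.04, 0.03 and 0.02. HOXC11, TBX5 and PITX1 reached at most 3.45, 3.69 and 3.60 in any array, below the median levels of 3.87 and 4.02, where signal above background is not shown. HOXA13, also chosen in advance, has no feature with a single gene symbol and was not analysed here. PMEL, a melanosome protein, differed by -0.26 (SE 0.13), LCE5A, a late cornified envelope protein, by 0.34 (SE 0.16), FCER1A, an IgE receptor subunit of Langerhans cells, by -0.38 (SE 0.16), KRT35, a hair keratin, by 0.07 (SE 0.05), and SFRP2, a dermal Wnt modulator, by -0.42 (SE 0.22).

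With all 16 arrays no gene list passed between those labelled volar and non-volar, with 0 of 34 lists called by camera or by fry and 2 at an unadjusted camera p under 0.05. The lowest adjusted p, 0.0714, was that of the immediate early genes, whose members JUN, FOS and EGR3 differed by -0.20, -0.18 and -0.17 and FOSB by 0.09. That list passed as lower without back of foot replicate 3 or 4 or palm replicate 3 (adjusted p 0.0127, 0.0476 and 0.0305), desmosome genes without palm replicate 1 (0.0145) and dermal matrix genes without sole replicate 1 (0.00184). With all arrays and an estimated correlation, each of these lists had a camera adjusted p of 0.927. At the preset correlation nerve and Schwann cell genes came next to the immediate early genes at 0.164, with CDH19 at 0.15 and S100B at 0.13. With p values adjusted over the list alone, 1 member each of the sweat gland and blood lists passed: CHRM3, the muscarinic receptor of sweat glands, at -0.47 (SE 0.11), and S100A12, a neutrophil protein, at 0.48 (SE 0.16). Over all features their limma adjusted p values were 0.965 and 1.0.

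Across all 21251 features limma called 0 at an adjusted p of 0.05, with 833 at an unadjusted p under 0.05 where 1062.55 are expected by chance, and the lowest adjusted p was 0.350. In simulated data of this size, with independent noise of equal spread in all sites, limma recovered 95 of 100 features changed by 1 on the log2 scale. The real sites differ in spread, and that recovery does not hold for a feature as variable as KRT9, with its SE of 1.42. Leaving out back of foot replicate 4 gave 2 called features and leaving out sole replicate 1 gave 1. Restricted to the 8 arrays labelled lower extremity, an alternative chosen after the data were seen, the count was also 0.

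Palm against back of hand, and sole against back of foot, ask whether the volar difference holds within each extremity. All 4 sites shared 1 variance per feature, although the median SD within a site was 0.105 for palm and 0.081 for back of hand. For sole and back of foot it was 0.172 and 0.162, so the hand test was conservative and the foot test liberal. Between the arrays labelled palm and back of hand limma called 0 features, with 165 at an unadjusted p under 0.05 where 1062.55 are expected by chance. Fitted alone, these arrays also gave 0. Between those labelled sole and back of foot limma called 8, of which 4 were higher in sole and 4 lower, with 1586 at an unadjusted p under 0.05. MLXIPL, a glucose-responsive transcription factor, was higher by 1.48 (SE 0.19), ND5, a mitochondrial subunit of respiratory complex I, by 1.17 (SE 0.17), and CALN1 by 0.58 (SE 0.09). MMS22L, a replication repair factor, was lower at -1.36 (SE 0.20), SP4, a transcription factor, at -1.27 (SE 0.20) and NREP at -1.20 (SE 0.18). The limma adjusted p values of these 6 genes ranged from 0.0236 to 0.0442, and none of the 6 was called when the 4 arrays of each site were fitted alone or with the replicate number as a block. Array weights ended the calls of ND5, CALN1, MMS22L and SP4, a trended robust prior those of ND5 and CALN1, and quantile normalization or the use of all features that of CALN1. The count of 8 depended on single arrays. It was 18 without sole replicate 2, 14 without back of foot replicate 1 or replicate 3, and 4, 2 and 2 without sole replicates 1, 3 and 4. It was 3 without back of foot replicate 2, 1 without palm replicate 1, and 0 without palm replicate 4, back of hand replicate 2 or back of hand replicate 4.

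The interaction asks whether the volar difference itself differed between hand and foot. No feature passed, with 792 at an unadjusted p under 0.05 by limma. The 6 smallest p values belonged to CALN1 (-0.74, SE 0.13), MLXIPL (-1.496, SE 0.27), CYP1B1, a xenobiotic-metabolising cytochrome (-0.41, SE 0.07), ZNF532, a zinc finger protein (-0.71, SE 0.13), ND5 (-1.18, SE 0.24) and ALG13, a glycosylation enzyme (0.37, SE 0.08), with adjusted p values from 0.443 to 0.597. With quantile normalization on top, ND5 passed at -1.45 (limma adjusted p 0.0424). Leaving out sole replicate 1 or sole replicate 3 gave 1 called feature each. Across features the palm and sole effects had a Pearson r of 0.048 and shared their sign in 50.9% of features.

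Upper against lower extremity is the other factor of the design. IGF2, a fetal growth factor (feature 3317217), had a level of 12.13 in the arrays labelled upper extremity and 4.80 in those labelled lower extremity, a difference of 7.33 (SE 0.23, n = 8 per side) or 161-fold. APOB, the lipoprotein of liver and gut, had 8.26 against 3.56, a difference of 4.70 (SE 0.06), and NTS, a gut and brain neuropeptide, was higher by 4.32 (SE 0.10). The other genes among the 10 largest were ACVR2B, an activin receptor (5.98, SE 0.34), LINC01443 (5.59, SE 0.20), PRTG, an embryonic cell adhesion protein (5.32, SE 0.20), RASEF (5.09, SE 0.28), PRDM15 (5.05, SE 0.20), PEG3-AS1 (4.92, SE 0.13) and PSIP1, a chromatin-binding coactivator (4.78, SE 0.51). At the other end FLJ42627 differed by -3.41 (SE 0.10), NANOS2, a germ cell factor, by -2.99 (SE 0.14), RPL23AP53 by -2.81 (SE 0.22), CDH7, a cadherin, by -2.72 (SE 0.22), CDKL3 by -2.68 (SE 0.15), PFN3 by -2.52 (SE 0.18), MIR181B2 by -2.33 (SE 0.27) and ATAD3C by -2.24 (SE 0.09).

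All 18 of these genes kept the arrays of the labelled extremities apart without overlap, and so did 77 of the 90 called genes named for this comparison. These genes were chosen by their difference or p value, so the chance share of 0.0155% for a gene not so chosen is no yardstick for them. In the arrays labelled lower extremity, ACVR2B, PRTG, RASEF, PEG3-AS1, APOB and NTS had mean levels below the median array level of 4.02, where signal above background is not shown. The same holds in the arrays labelled upper extremity for NANOS2, RPL23AP53, CDH7, CDKL3 and ATAD3C, below 3.87, so the size and order of these differences rest on that floor. Features of 1 gene did not always move together: 2 of 3 features of IGF2, 1 of 2 of LINC01443, 1 of 2 of PRDM15, 4 of 10 of FLJ42627 and 1 of 6 of RPL23AP53 were called in the stated direction. Limma called 16370 features (77.0%) in 14202 genes, 5547 higher and 10823 lower in the arrays labelled upper extremity. Of these, 1696 differed by at least 1 on the log2 scale, 1378 higher and 318 lower. The median difference over all features was -0.19, and quantile normalization moved it to -0.06, so differences of gene groups are given from here on relative to that median. Quantile normalization also moved the share of called features that were higher from 33.9% to 43.3%, and a filter on dim features to 53.0%.

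**Figure D3:**
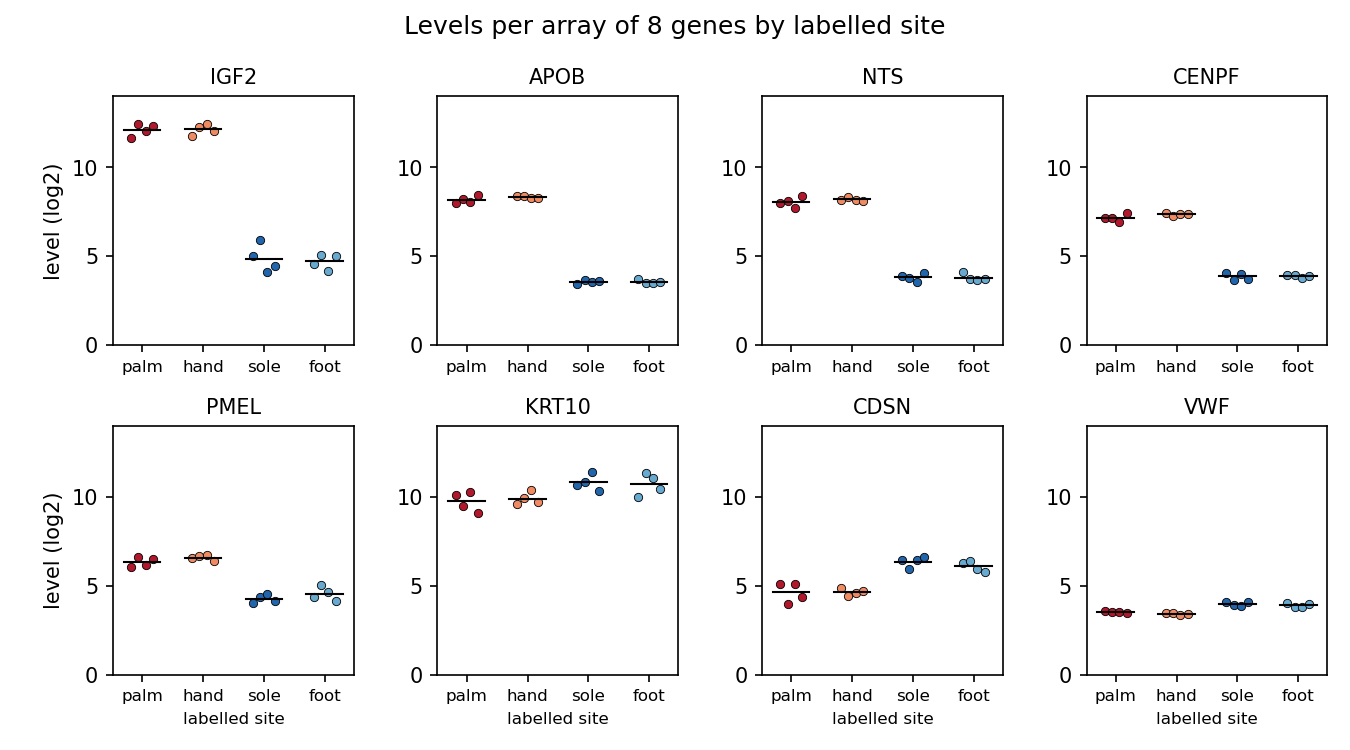
Levels (log2, vertical axes) of 8 genes in each of the 16 arrays by labelled site, with 1 point per array and a line at the mean of each site (n = 4). IGF2, APOB, NTS, CENPF and PMEL lie higher in the arrays labelled palm and back of hand, and KRT10, CDSN and VWF lower, also after quantile normalization.

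Some markers of lineages found in cell line pools moved with the labelled extremity, in the same arrays as every group below. Of 54 measured markers of 7 such lineages, of which T cells, plasma cells, myeloid cells and pigment cells can also occur in skin, 15 (27.8%) were higher by a raw difference of at least 0.5 in the arrays labelled upper extremity, against 0 of 49 markers of 8 other lineages (2-sided Fisher exact p 2.51e-05). Over all features 15.4% passed the same cut. The other 39 markers of the pool lineages were not higher by 0.5, and 28 of the 54 were called lower. Of the 49 markers of other lineages 42 were called lower. A Fisher test against them therefore does not set the pool markers against genes in general. The Fisher p values here and below also treat markers as independent, although all were measured on the same arrays, and may be too small. With 0.5 taken relative to the median, an alternative chosen after the data were seen, 20 of 54 (37.0%) and 1 of 49 (2.04%) were higher (Fisher exact p 4.37e-06). The median is negative, so this cut is looser than the raw one. The share of all features that pass it was not counted and is at least 15.4%. The lists were written after the first results had been seen. Of their members CD3D, CD3G and LCK also belong to the T cell list already tested, and the values of the others had not been looked at.

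Proliferation genes were higher in the arrays labelled upper extremity. Of 21 measured members 19 were higher, 1 lower and 1 not called, the same over all features and adjusted over the list alone, with a relative median of 2.11 (19 higher and 0 lower after quantile normalization). TOP2A, the DNA topoisomerase of dividing cells, was higher by 3.63, CENPF, a centromere protein, by 3.58, MKI67, the Ki-67 antigen, by 3.13 and BUB1, a spindle checkpoint kinase, by 2.12 (SE 0.10, 0.08, 0.08 and 0.05). This was the only one of 34 lists that camera called, at an adjusted p of 1.76e-12, and its call was lost at adjusted p = 0.480 with an estimated correlation. Fry, which asks whether genes move one way without setting them against other genes, called 28 of the 34 lists, and 8 lists had an unadjusted camera p under 0.05. The call counts of members below test each gene against no difference, not against the median. Counts after quantile normalization are made anew and need not hold the same members.

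Pigment cell genes had 8 of 14 members higher, 2 lower and 4 not called, with a relative median of 0.60 and an adjusted p of 0.0685. PMEL and MLANA, melanosome proteins, were higher by 2.24 and 1.02 (SE 0.13 and 0.10), MITF by 1.46 (SE 0.07) and EDNRB, the endothelin receptor of melanoblasts, by 1.20 (SE 0.09). Quantile normalization kept 7 of the 8 higher members and brought the list past the threshold (adjusted p 0.0254), as did the replicate block (0.0440), but on the deposited values it had an adjusted p = 0.927 with an estimated correlation. Leaving out palm replicate 1, sole replicate 2, back of foot replicate 3 or back of foot replicate 4 did so too, at 0.0404, 0.0428, 0.0423 and 0.0476. Targets of the mechanosensitive factor YAP had 7 of 11 members higher and 3 lower (6 and 2 after quantile normalization), with a relative median of 0.40 and an adjusted p of 0.184. All 6 were among the 7, but 0 of the 3 lower members were called lower in both. TEAD1, the DNA-binding partner of YAP, was higher by 2.08 (SE 0.17), NT5E, an ectonucleotidase, by 1.86 (SE 0.05) and CCN1, a matricellular protein, by 0.93 (SE 0.13).

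Most called members of the epidermal lists were lower in the arrays labelled upper extremity, as were 10823 of the 16370 called features, and no epidermal list passed camera on the deposited values. All 7 interfollicular keratins were lower, also after quantile normalization, with a relative median of -0.75 and an adjusted p of 0.430. KRT10, the suprabasal keratin, was at -0.75 (SE 0.23), KRT78 at -0.62 (SE 0.16), KRT15, a basal keratin, at -0.61 (SE 0.18) and KRT80 at -0.49 (SE 0.08). In the cornified envelope list 17 of 21 members were lower and 4 not called (15 lower after quantile normalization), with a relative median of -0.56 and an adjusted p of 0.234. Its members CDSN, the corneodesmosome protein, KLK5, a desquamation protease, and the transglutaminases TGM3 and TGM1 were at -1.39, -0.70, -0.59 and -0.46 (SE 0.16, 0.09, 0.08 and 0.07). Barrier lipid synthesis had 15 of 19 members lower and 4 not called (14 lower after quantile normalization), with a relative median of -0.31 and an adjusted p of 0.0998. There CYP4F22, a fatty acid omega-hydroxylase, was at -0.60, ALOX12B and ALOXE3, barrier lipoxygenases, at -0.46 and -0.31, and FA2H, a fatty acid hydroxylase, at -0.29 (SE 0.06, 0.07, 0.05 and 0.05). ALOXE3 and FA2H reached at most 3.36 in the arrays labelled upper extremity and 3.89 in the others, below the medians of 3.87 and 4.02. CYP4F22 and ALOX12B had at least 4.34 and 4.06 in the arrays labelled lower extremity. Whether the barrier lipid list fell more than dim features in general was not tested. After quantile normalization the cornified envelope and barrier lipid lists passed camera (adjusted p 0.0147 each). On the deposited values both had an adjusted p = 0.927 with an estimated correlation.

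Genes of keratinocyte defence showed the same direction, with 12 of 15 members lower and 3 not called (9 lower after quantile normalization), a relative median of -0.34 and an adjusted p of 0.228. S100A9, a calprotectin subunit, was at -1.36 (SE 0.17), RNASE7, an antimicrobial ribonuclease, at -1.05 (SE 0.16) and DEFB1, a defensin, at -0.83 (SE 0.15). Genes mutated in inherited palmoplantar keratoderma had 2 of 19 members higher, 15 lower and 2 not called (3 higher and 14 lower after quantile normalization), a relative median of -0.38 and an adjusted p of 0.493. TRPV3, a heat-gated channel, was at -0.32 (SE 0.06), RHBDF2, an inactive rhomboid, at -0.24 (SE 0.04), and CTSC, a lysosomal protease, was higher by 0.71 (SE 0.07). Desmosome and adhesion genes had 3 of 17 members higher and 12 lower, or 13 lower when adjusted over the list alone, with a relative median of -0.15 that quantile normalization moved to -0.62, with an adjusted p of 0.591. DSG2, a desmosomal cadherin, was higher by 1.67 (SE 0.06), and JUP, plakoglobin, was at -0.38 (SE 0.09). All 11 blood endothelium genes were lower (10 after quantile normalization), with a relative median of -0.28 and an adjusted p of 0.0609. ESAM, VWF and TIE1, endothelial adhesion, clotting and receptor proteins, were at -0.41, -0.28 and -0.28 (SE 0.05 each). Their levels reached at most 3.59 in the arrays labelled upper extremity, below the median level of 3.87. In the others they reached at most 4.19, near the median of 4.02. Marker lists of the other lineages set against the cell line pool also had negative relative medians, from -0.34 (pancreas acinus) to -0.04 (cardiac muscle). Whether the endothelium list fell more than dim features in general was not tested. The endothelium list passed after quantile normalization (adjusted p 0.0422), with the replicate block (0.0440), and without palm replicate 1 or 3, sole replicate 1 or 2, or back of foot replicate 3 or 4 (0.0245 to 0.0476). On the deposited values it had an adjusted p = 0.927 with an estimated correlation.

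**Figure D4:**
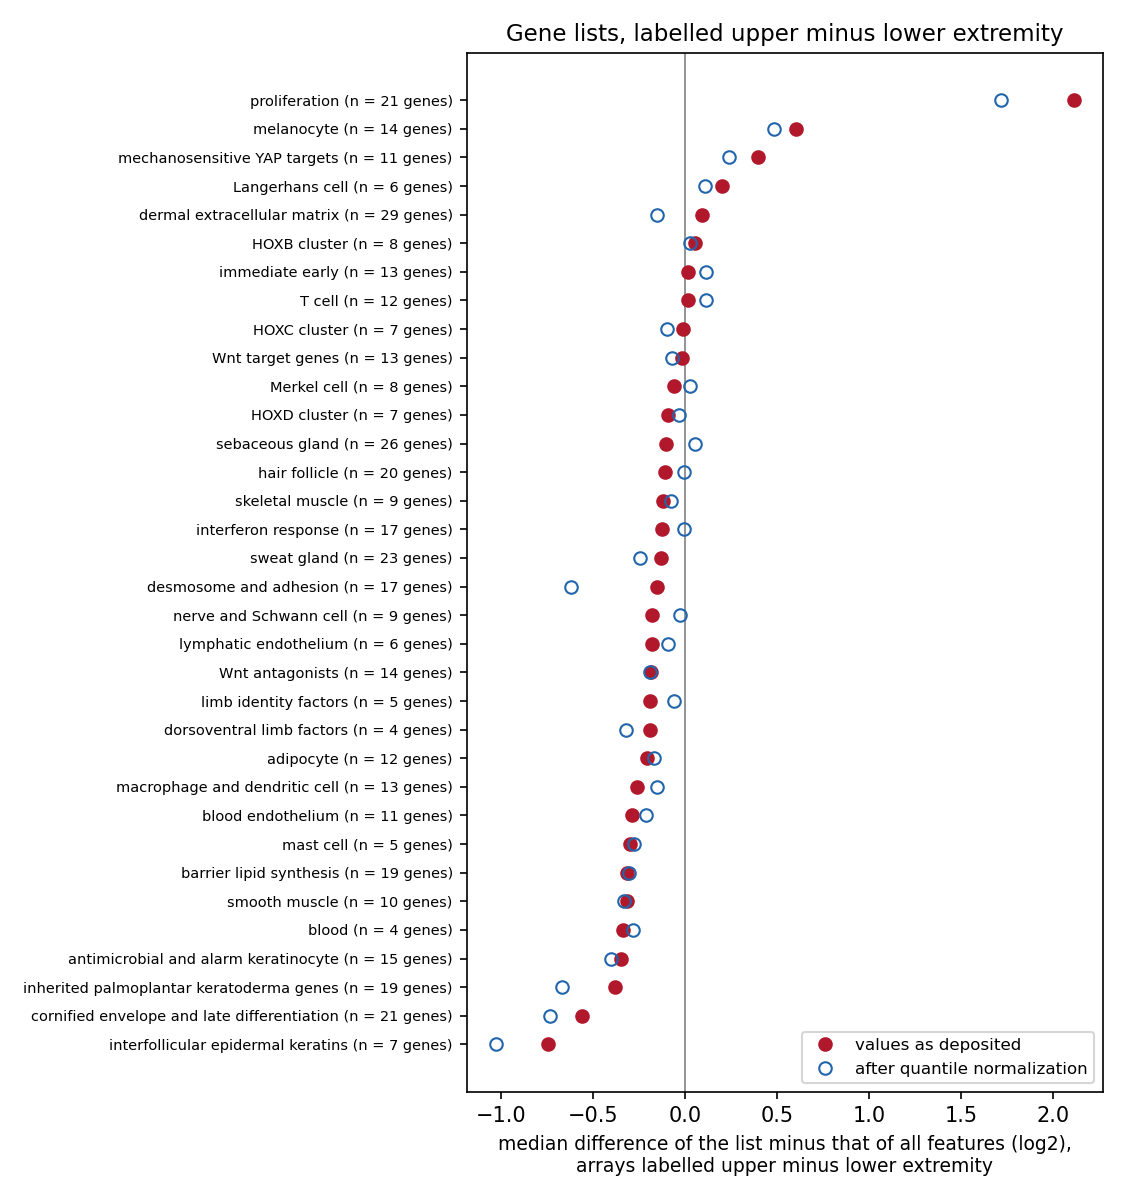
Median difference of each of 34 gene lists minus that of all features (log2, horizontal axis), arrays labelled upper minus lower extremity, with filled points for the deposited values and open points after quantile normalization; the number of measured genes stands beside each list. Proliferation lies farthest to the right at 2.11 and the interfollicular keratins farthest to the left at -0.75, and the dermal matrix (0.09 and -0.15), sebaceous gland (-0.10 and 0.05) and Merkel cell (-0.06 and 0.03) medians change sign between the 2 scalings.

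TBX5, which specifies the forelimb, and TBX4 and PITX1, which specify the hindlimb, were at -0.19, -0.15 and 0.06 relative to the median (SE 0.06, 0.06 and 0.05). After quantile normalization TBX5 and TBX4 were no longer called (adjusted p 0.150 and 0.0667). PITX1 was lower by limma with a raw difference of -0.13 (adjusted p 0.0307), turned to 0.16 after quantile normalization (adjusted p 0.0277), and lost its call without back of foot replicate 2, back of hand replicate 1, 3 or 4, palm replicate 2, or sole replicate 2 or 4 (adjusted p 0.0511 to 0.0609). All 5 limb identity genes were called lower, 2 lower and 1 higher after quantile normalization, with TBX18 and ISL1, limb bud factors, at -0.33 and -0.22. TBX5, TBX4, PITX1 and ISL1 reached at most 3.36, 3.62, 3.39 and 2.89 in the arrays labelled upper extremity, below the median level of 3.87. In the others they reached at most 3.69, 4.03, 3.60 and 3.44, with a median level of 4.02. Signal above background is not shown there, so these differences rest on low signal. The dorsoventral limb genes were called lower in 4 of 4 (2 after quantile normalization), with LMX1B at -0.41 (SE 0.15) and EN1 at -0.22 (SE 0.08). WNT7A was at -0.05 (SE 0.07) and lost its call after quantile normalization (adjusted p 0.765).

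Of the HOX clusters, which encode positional transcription factors, HOXB had 2 of 8 members higher and 5 lower, HOXC 3 of 7 lower and HOXD 5 of 7 lower. After quantile normalization HOXB had 3 higher and 0 lower, HOXC 2 lower and HOXD 3 lower. HOXB9 was higher by 0.76 (SE 0.08), and HOXC9, HOXD3 and HOXD10 were at -0.58, -0.34 and -0.24 (SE 0.08, 0.08 and 0.07). HOXC10, HOXC11 and HOXD13 were not called, at -0.01, 0.09 and 0.07, but without back of foot replicate 4 HOXC10 and HOXD13 passed as lower, with raw differences of -0.30 and -0.18 (adjusted p 0.0196 and 0.0247). HOXC11 reached at most 3.45 in any array, below the median levels of 3.87 and 4.02. KRT9 was not called at -0.68 (SE 1.42). Wnt antagonists had 2 of 14 members higher and 10 lower (2 and 6 after quantile normalization), with DKK1 higher by 0.84 (SE 0.06) and WIF1 at -0.47 (SE 0.09). Wnt target genes had 3 of 13 higher and 8 lower (3 and 5 after quantile normalization). Among them LEF1, a Wnt transcription factor, and BAMBI, a TGF-beta decoy receptor, were higher by 1.66 and 2.39, and APCDD1, a Wnt inhibitor, was at -0.70 (SE 0.05, 0.10 and 0.12).

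Palm against sole and back of hand against back of foot repeat the extremity comparison within each kind of labelled skin. Differences here are raw, not relative to the median. IGF2 was higher by 7.25 (SE 0.33) in the arrays labelled palm and by 7.42 (SE 0.33) in those labelled back of hand. ACVR2B was higher by 6.05 and 5.92 (SE 0.49 each), and LINC01443 by 5.81 and 5.37 (SE 0.28 each). FLJ42627 was at -3.20 and -3.63 (SE 0.14 each), NANOS2 at -2.94 and -3.04 (SE 0.19 each), and RPL23AP53 at -3.12 (SE 0.31) in back of hand against back of foot. Limma called 13601 features between palm and sole, 4665 higher and 8936 lower, and 14130 between the backs of hand and foot, 4935 higher and 9195 lower. The share higher was 34.3% and 34.9%, 46.4% and 46.1% after quantile normalization, and 54.4% and 55.2% with the filter on dim features, where most called features were higher.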

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

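The genes checked here were those named in the text, and the checks of SPINK6 and of the other genes outside the naming rule were chosen only after their values were seen. In 492 checks of a gene within 4 arrays of a labelled site, 22 had 1 array far from the other 3, where chance alone gives about 1 in 20 checks. Each ratio below is the gap of that array to its nearest neighbour over the whole range, with a critical value of 0.829.

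SPINK6, a protease inhibitor of the epidermis, was highest in replicate 1 of every labelled site and passed the critical value in 3, with ratios of 0.905 in palm (6.09 against a mean of 3.53 in the others), 0.898 in sole (6.84 against 3.93) and 0.85 in back of hand (6.82 against 3.47), and levels of 5.27 against 3.88 in back of foot. Among positional genes the ratio was 0.949 for HOXC9 in sole replicate 1, 0.927 for HOXC11 in palm replicate 3 and 0.841 for TBX5 in back of foot replicate 3. FBN1, the elastic microfibril protein, had 0.952 in sole replicate 1 (4.93 against 4.07) and 0.891 in back of foot replicate 3 (4.60 against 4.14). Of the genes with large extremity differences, RASEF had 0.961 in sole replicate 3 (4.05 against 2.50), APOB 0.904 and NTS 0.87 in back of foot replicate 1, and NANOS2 0.857 in palm replicate 1. For defence and immune genes the ratio was 0.911 for S100A9 in palm replicate 1 (4.88 against 4.14), 0.87 for RNASE7 in back of foot replicate 4 (4.50 against 5.39), 0.862 for LYZ in palm replicate 3 and 0.85 for S100A12 in sole replicate 4 (4.99 against 3.73). CHRM3, the sweat gland receptor, had 0.883 in palm replicate 3 and 0.839 in sole replicate 2. The remaining ratios were 0.918 for ESAM in back of foot replicate 2, 0.892 for JUN in palm replicate 2, 0.882 for KRT35 in back of foot replicate 4 and 0.843 for RHBDF2 in back of hand replicate 3.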

How the results depend on the processing

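The alternatives on replicate numbers and on the arrays labelled lower extremity alone were chosen only after the data were seen. The filter on dim features gave 9702 features between labelled extremities, 8092 between palm and sole and 8391 between the backs of hand and foot, with fewer features tested. Quantile normalization gave 1 for the interaction, 17 for sole minus back of foot, 9404 between the backs of hand and foot, and 5 lists for the extremity; the cause was not tested. All features of the table gave 1 for volar minus non-volar, 32057 for the extremity, 1 for the interaction, 17 for sole minus back of foot, 24865 for palm minus sole and 26133 for the backs of hand and foot, with more features tested. The fit of the compared sites alone and the replicate block each gave 0 for sole minus back of foot, the block 3 lists for the extremity, and array weights 2 features for sole minus back of foot; the cause was not tested. An estimated correlation gave 0 lists for the extremity. A minimum difference of 1 left 1696, 5, 1651 and 1785 features for the extremity, sole minus back of foot, palm minus sole and the backs of hand and foot, by its construction. For PITX1, quantile normalization reversed the extremity difference to 0.16, and the cause was not tested. Offsets of 1 and 64 before a log transform were not run, since the values are logarithmic already.

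With single arrays left out the counts ranged from 0 to 2 for volar minus non-volar, 15906 to 16447 for the extremity, 0 to 1 for the interaction, 0 to 0 for palm minus back of hand, 0 to 18 for sole minus back of foot, 12376 to 13812 for palm minus sole and 12944 to 14382 for the backs of hand and foot. Lists ranged from 0 to 1 for volar minus non-volar, with 1 without back of foot replicate 3 or 4, palm replicate 1 or 3, or sole replicate 1. For the extremity they ranged from 1 to 3, with 3 without back of foot replicate 3 or 4, palm replicate 1 or sole replicate 2, and 2 without palm replicate 3 or sole replicate 1. The lists added were immediate early, desmosome or dermal matrix genes for the volar comparison and blood endothelium and melanocyte genes for the extremity.

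For the named genes, 1070 results under other settings kept their direction and side of the threshold, 24 lost their call, 2 gained one and 1 reversed, and with single arrays left out 2656 kept theirs, 60 lost and 4 gained a call. A change of sign where neither value was called counts as kept. Among lists, 389 results kept theirs, 1 lost and 6 gained a call, and 1073 and 15 kept and gained with single arrays left out. Whether the replicate numbers pair arrays was checked on residuals: same-number pairs had correlations across features from -0.14 to 0.28 (median 0.086), 10 of 24 above 0.1, and different-number pairs had a median of -0.017, 10 of 72 above 0.1. Of 16 arrays 9 correlated best with an array of their own number, so sharing by number stays open; the labels do not state it, and the numbers served as a block in an alternative only. Between replicate numbers the count of 4 was 4 with the filter, 2 after quantile normalization and 9 with all features. Levels near 3 to 4 on the log2 scale, where many named genes lie, are close to the array medians, and differences there rest on low signal.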

Other observations

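The tests on replicate numbers, on array scale, on donor differences in KRT9, on the share of epidermis and on markers of cell lines were chosen only after the result that prompted them was seen.

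Gland and stromal genes, compared between the labelled extremities relative to the median of all features, went both ways. Sebaceous genes had 10 of 26 members higher in the arrays labelled upper extremity and 14 lower (11 and 9 after quantile normalization), with SOAT1, a sterol esterification enzyme, and FADS1, a fatty acid desaturase, higher by 2.09 and 1.87. Their median was -0.10, 0.05 after quantile normalization, while their mean raw difference was 0.19 and camera ranked them higher (adjusted p 0.657). Sweat gland genes had 3 of 23 higher and 14 lower (2 and 12), with KRT8, a simple epithelial keratin, higher by 0.60 and EHF at -0.52, and KRT18 higher by 0.85 but not called after quantile normalization (adjusted p 0.244). Of them 1 was higher and 11 were lower in both. Hair follicle genes had 2 of 20 higher and 13 lower (4 and 5), with FOXN1, a follicle factor, at -0.33. Dermal matrix genes had 7 of 29 higher and 13 lower (5 and 11), with FBN1 and TNC, microfibril and tenascin genes, higher by 1.22 and 1.04 and ELN, elastin, at -0.34. Smooth muscle had 1 of 10 higher and 8 lower (0 and 8), skeletal muscle 1 of 9 and 7 (2 and 4), adipocytes 1 of 12 and 9 (3 and 6), nerve and Schwann cells 0 of 9 and 6 (0 and 3) with CDH19 at -0.34, lymphatic vessels 1 of 6 and 4 (2 and 4), and Merkel cells 2 of 8 and 5 (3 and 2), with PIEZO2, a touch channel, higher by 1.96.

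Immune genes also split. Macrophage and dendritic cell genes had 2 of 13 higher and 10 lower, 11 lower adjusted over the list alone, and 2 and 8 after quantile normalization. LYZ, lysozyme, and CD68, a lysosomal protein, were higher by 2.56 and 1.24, while VSIG4 and C1QC, tissue macrophage genes, were at -0.49 and -0.58. T cell genes had 3 of 12 higher and 7 lower (5 and 2), with the receptor subunits CD3G and CD3D higher by 1.57 and 1.44 and CD8A at -0.39. Langerhans cells had 2 of 6 higher and 2 lower (2 and 1), with FCER1A higher by 1.05. Mast cells had 3 of 5 lower, 5 adjusted over the list alone and 2 after quantile normalization, and blood cells 3 of 4 (2). Interferon response genes had 1 of 17 higher and 12 lower, 13 adjusted over the list alone and 1 and 3 after quantile normalization. The higher gene was not the same in both. Immediate early genes had 4 of 13 higher and 6 lower (4 and 2), with EGR1 higher by 1.10 and EGR3 at -0.68. None of these lists passed camera, and for T cell, Merkel cell and Wnt target genes the raw median was negative while the mean was positive.

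The arrays labelled upper extremity differed from the others over most features, and a candidate explanation is that they hold RNA of a pool of several human cell lines. Markers of the lineages of such lines were higher by a raw difference of 0.5 in 27.8% (15 of 54), against 0 of 49 markers of other lineages and 15.4% of all features, by 0.5 relative to the median in 20 of 54 against 1 of 49, and by a raw 0.5 in 25.5% without 3 genes shared with the T cell list (Fisher exact p 0.000104). For the cut relative to the median the share of all features was not counted. Of the 7 pool lists the hepatocyte, embryonal carcinoma, T lymphoblast, plasma cell and breast lists had 6 of 11, 3 of 6, 3 of 11, 2 of 9 and 1 of 7 higher, and the melanoma and myeloid lists 0 of 3 and 0 of 7, on the raw scale; levels of the most abundant were 8.86 against 7.59 for LIN28A, 7.14 against 4.12 for TFF1, 6.24 against 3.31 for L1TD1 and 6.16 against 3.67 for ITIH2. For 1 liver-like cell type alone the prediction was that none of the 6 other pool lists would pass 20%, and 3 did. Without the 3 shared genes the T lymphoblast list had 1 of 8. All non-hepatocyte pool markers then had 7 of 40 (17.5%, Fisher exact p 0.00271 against the other lineages). That share is near the 15.4% of all features, so 1 cell type alone stays open. These Fisher p values treat markers measured on the same arrays as independent and may be too small. The tables argue against array scale as the whole cause. IGF2 still differed by 7.08 after quantile normalization, and 63.6% of the calls were made again in the same direction. A biological difference between hand and foot stays open and untested. In the arrays labelled lower extremity 15 of the 54 pool markers lay above the median level of 4.02, not the same set as the 15 that were higher.

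KRT9 followed the replicate number (11.77 ± 0.26, 7.38 ± 1.73, 5.76 ± 1.31 and 11.40 ± 0.64 in numbers 1 to 4, SD, n = 4 each), with a 2-sided exact permutation p of 0.00123 (17 of 13824 arrangements), and site labels that do not match the biopsies are a candidate explanation. Donor differences with correct labels would leave KRT9 higher in volar skin within a number; the blocked difference, from the same values as the pattern, had an upper 95% limit of 1.17, which argues against a volar excess of 2 or more, a bound set after the values were seen, and more epidermis in some biopsies would raise epidermal keratins together, but in deviations from the site means KRT1 ran with KRT9 (r = 0.85, permutation p 0.00074) and KRT2, the keratin of thin interfollicular epidermis, ran opposite (Pearson r = -0.695, permutation p 0.00785, Spearman rho -0.74, permutation p 0.00252, n = 16). That r was -0.64 without the 2 arrays farthest from the median, -0.79 and -0.59 within the arrays labelled lower and upper extremity, and its adjusted p 0.0235 over 6 relations. The permutation p values here and below treat the 16 arrays as independent within sites. KRT9, KRT1 and KRT2 all varied with the number (limma unadjusted p 4.42e-06, 6.35e-05 and 8.70e-05). If a number marks 1 donor, which stays open, those permutation p values are too small. Mismatched labels cannot be told apart from other accounts. The mean of 10 melanocyte genes, predicted to fall where KRT9 is high, had r = -0.359 (permutation p 0.219, rho -0.41, permutation p 0.134, -0.49 without the 2 farthest, -0.23 and -0.50 within the lower and upper labels, adjusted p 0.263), between the limits set in advance. The sweat gland list, which should then rise with KRT9, ran against that account without passing (r = -0.44, permutation p 0.127). That r was -0.10 without the 2 farthest, and -0.92 and 0.08 within the lower and upper labels. Numbers that mark body sites stay open as well, since 3.57% (1 of 28) of HOX and limb genes, too few to decide, against 5.31% of all features had an unadjusted p under 0.05 between numbers.

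Between replicate numbers limma called 4 features, in SPINK6, CSRP2, KRT9 and FABP5 (adjusted p 0.0275 each), 1 in the arrays labelled lower extremity alone and 0 in those labelled upper extremity. Over all 16 arrays 1128 features had an unadjusted limma p under 0.05 between numbers, where 1062.55 are expected by chance. SPINK6 had a mean level of 6.25 in number 1 and of 3.65 to 3.76 in the others. In numbers 1 to 4, CSRP2, a LIM domain protein, had 10.45, 8.09, 8.67 and 10.54, and FABP5, the epidermal fatty acid binding protein, 8.45, 6.80, 7.48 and 8.08. KRT1, the suprabasal partner keratin, ran with KRT9 in deviations from the site means (r = 0.85, permutation p 0.00074, rho 0.85, permutation p 0.00061, r = 0.87 without the 2 farthest, 0.84 and 0.86 within the arrays labelled lower and upper extremity, adjusted p 0.00444, 6 relations). KRT10 had r = -0.60 (permutation p 0.0314, rho -0.49, permutation p 0.0747, -0.49 without the 2 farthest, -0.80 and -0.37 within the lower and upper labels, adjusted p 0.0628). The hair follicle list, scarce in volar skin, had r = -0.14 (permutation p 0.653, rho -0.12, permutation p 0.675, -0.30 without the 2 farthest, 0.21 and -0.39 within the lower and upper labels, adjusted p 0.653). The sweat gland list, abundant in volar skin, had r = -0.44 (permutation p 0.127, rho -0.43, permutation p 0.132, -0.10 without the 2 farthest, -0.92 and 0.08 within the lower and upper labels, adjusted p 0.190). Against 5.31% of all features, members with an unadjusted p under 0.05 between numbers were 5 of 7 interfollicular keratins, 8 of 19 keratoderma genes, 7 of 17 desmosome genes, 8 of 23 sweat gland genes, 3 of 5 mast cell genes, 6 of 21 cornified envelope genes and 4 of 14 melanocyte genes, and in 9 of 34 lists, among them HOXB, HOXD, interferon, immediate early and macrophage genes, there were 0, without a test of these shares.

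Regrouping the arrays counted how many other splits gave as many calls. For the extremity 1 of 100 splits gave as many features, the real one with 16370 against 10807 at most in the others. For palm minus sole and the backs of hand and foot it was 1 of 35 each (13601 and 14130 against 1 each). Of 35 splits 1 is the smallest possible share, and every other split mixes arrays of both labelled extremities. Between replicate numbers 1 of 100 gave as many (4 against 1). That test was chosen after KRT9, 1 of the 4, was seen to follow the numbers, so it gives no independent support. Chance was not excluded for sole minus back of foot (10 of 35, 8 against 2850) or for the lists of the extremity (83 of 100, 1 against 10). Where the real count was 0 every split gives as many, so the splits decide nothing there: volar minus non-volar (100 of 100, 12775 at most in the others, and 100 of 100 within extremities, 55 at most), the interaction (100 of 100, 1 at most), palm minus back of hand (35 of 35, 0 at most) and the volar lists (100 of 100, 12 at most). The splits of 12775 and 10807 features each had 7 of the 8 arrays labelled upper extremity on 1 side, a structure by labelled extremity. The split of 2850 set back of foot replicates 1 and 4 and sole replicates 2 and 4 against the other 4 arrays labelled lower extremity. That structure follows neither site nor number but the spread of values per array. The first 4 arrays had an SD across features of 0.947 to 1.02 and the other 4 of 1.06 to 1.10, without overlap. The cause was not tested.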
